A study of Mus musculus with 2 samples.

How the data were processed

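Gene expression was measured by RNA sequencing in 2 mouse medulloblastomas, 1 per genotype. Medulloblastoma is a tumour of the cerebellum, and SmoM2 is an activated form of Smoothened, the receptor component that switches on Hedgehog signalling. Both animals carried a tamoxifen-inducible Cre recombinase (CAG-CreER) and the SmoM2 transgene (Rosa26-SmoM2), and both received 10 tamoxifen injections. One carried wild-type Brg1 alleles and the other Brg1 alleles flanked by loxP sites. Brg1 is the protein of the gene Smarca4, an ATPase of the BAF chromatin remodelling complex. Total RNA came from dissected tumour tissue, which can hold cells other than tumour cells. The genotype labels do not limit the recombination to tumour cells.

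The deposited values are FPKM, fragment counts scaled to transcript length and to the mapped fragments of the library, per gene, with a lower bound, an upper bound and a status for each value, per the file headers. The submitters' processing notes list the mouse build mm10 and Cuffdiff 2.1.1, without a role for either. The aligner, the annotation, the filters and the way the bounds were made are not given in the sources used here. The files give no read counts, so the depth of each library is unknown. A search for steps of whole reads among 650 genes under 0.05 FPKM in both libraries put most ratios of knockout to wild type near no single value (the fullest log2 bin, from -0.3 to -0.2, held 50 genes), and no reads were recovered. Start positions in the files count from 0. Of 20737 symbols found in GENCODE M21, 52.0% had a matching start when counted this way and 4.9% when counted from 1. Coordinates below count from 1 on mm10.

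The table held 23746 records for 23284 gene symbols, 240 of them at several loci. Records with at least 1 FPKM in at least 1 library were called expressed and analysed. There were 13279 of these, and 10467 records stayed under 1 FPKM in both libraries. For each record the log2 ratio was log2((knockout FPKM + 1)/(wild-type FPKM + 1)). The added 1 FPKM makes ratios of low genes smaller than they are on the FPKM scale. A fixed rule of size, a log2 ratio of at least 1 or at most -1, took the place of a test. With 1 library per genotype there is no replicate check, no error and no p-value for any difference, and a difference between these 2 libraries can come from the animals as well as from the genotype.

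Gene lists for pathways, complexes, sample quality and cell types were fixed before the data were examined, 37 in all, of which 33 had at least 3 expressed members. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. If members varied independently of each other, 1.7 of 33 lists would do so by chance. Members of a real list can vary together and some genes are in several lists. The number of lists that stood apart therefore cannot be set against 1.7. The percentile describes these libraries and is not a test of the genotypes. Median log2 ratios of chromosomes were placed the same way.

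Genes named in the text were chosen by a rule also fixed beforehand. It took Smarca4, and the 10 highest and 10 lowest log2 ratios among genes of at least 5 FPKM in 1 library, without unnamed models and without small RNA genes known by the start of their symbol (Mir, Snor, Scarna, Rnu or n-R5). The short record AF357425 has none of these symbols and so was kept. It took up to 4 members of each list with the largest absolute log2 ratio of at least 1, or the 2 most abundant members where fewer than 2 reached it. It added Gli1, Gli2, Ptch1, Atoh1, Mycn, Ccnd1, Ccnd2, Mki67 and Smarca2. Some genes that the rule took are not reported here. Other list members named below were chosen after their values were seen.

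Alternatives set beforehand were pseudocounts of 0.1 and 0.5, FPKM rescaled to the same sum in each library (as TPM is), division by the upper quartile, centring on the median, other filters on low values, no small RNA genes, thresholds of 1.5-fold and 4-fold, and other ways to summarise a list. Chosen after seeing the data were the midpoint of the deposited bounds in place of FPKM, leaving out records with status FAIL or LOWDATA, and leaving out genes at several loci. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

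The scripts were tested on simulated data for this comparison, with 13279 genes and an assumed noise of 0.25 (SD, log2). The 2-fold rule recovered 99 of 100 genes made to differ 4-fold and 90 of 100 made to differ 3-fold, and 28 genes with no difference passed it. Of 1000 lists with no shift 52 lay outside the percentile limits. The test at first used the first 200 of these lists, of which 20 lay outside, and was then enlarged to 1000. These lists were random genes with independent noise, so they do not give the rate for lists whose genes vary together. All 50 lists shifted by 0.8 on the log2 scale lay above the upper limit. The assumed noise was not measured here, since it needs replicates.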

Results

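The data were 2 RNA sequencing libraries from SmoM2-driven medulloblastomas of mice, 1 from a tumour with wild-type Brg1 and 1 from a Brg1 knockout tumour. The comparison addresses how gene expression in this Hedgehog-type tumour differs when Brg1, the ATPase encoded by Smarca4, is deleted. At least 1 FPKM was reached by 12006 records in the wild-type library and by 12994 in the knockout library. FPKM summed to 388032 in the wild-type library and 343028 in the knockout library. Small RNA genes took 14.1% of the FPKM sum in the wild-type library and 7.12% in the knockout library, and cytosolic ribosomal protein genes took 13.3% and 6.43%. There was 1 library per genotype, so the values below carry no error, and "higher" and "lower" compare these 2 libraries. Xist and Y-linked genes also differed between them, so the sex of the animals may differ along with the genotype.

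Smarca4 (chromosome 9, 21616169 to 21704230, mm10), the targeted gene, had 14.05 FPKM in the wild-type library and 3.76 FPKM in the knockout library. The knockout value was 26.8% of the wild-type value (log2 ratio -1.66). Cell cycle genes, which were not targeted, had a median of 24.8%, so the Smarca4 value alone does not show the deletion. FPKM of the whole gene covers exons outside the deleted part, so it does not measure the share of cells with the deletion. Smarca2, the gene of the alternative BAF ATPase Brm, had 10.7 FPKM in the wild-type and 14.1 FPKM in the knockout library (log2 ratio 0.37), but its log2 ratio was -1.48 from the midpoints of the deposited bounds, so no direction can be given.

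Of 13279 expressed records, 2139 (16.1%) were at least 2-fold higher and 1151 (8.7%) at least 2-fold lower in the knockout library. Higher records made up 65.0% of these. The median log2 ratio was 0.09, with an interquartile range of -0.41 to 0.68. When FPKM was rescaled to the same sum in each library, the median was 0.26, and 3098 records were higher and 1024 lower, so that 75.2% were higher. List medians are given on the deposited scale. Of the 33 lists placed among random lists, 22 stood apart, 13 above and 9 below.

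**Figure D1:**
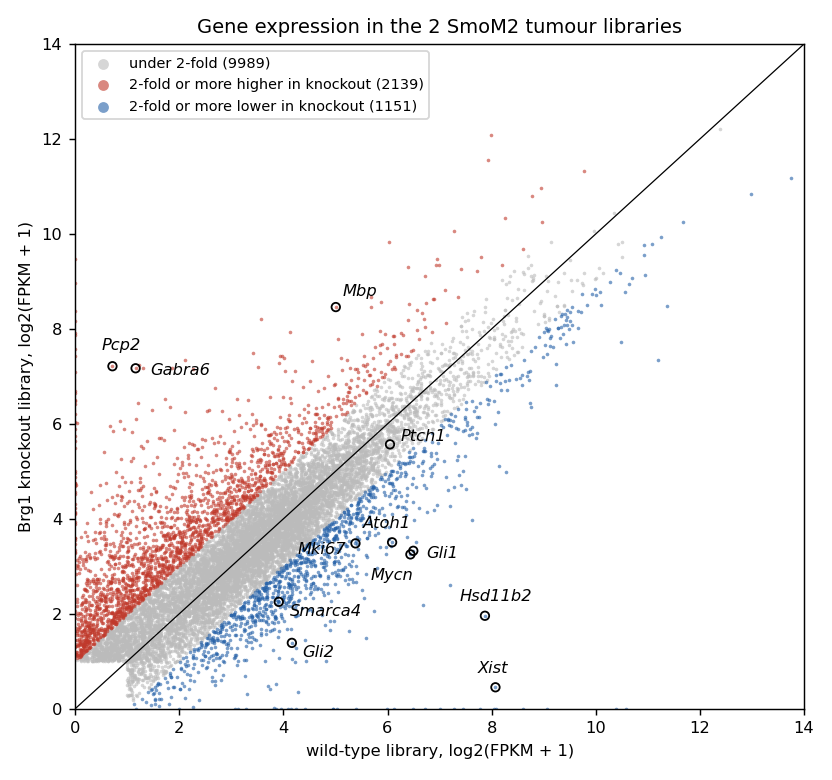
Each point is 1 of 13279 expressed records, with log2(FPKM + 1) in the wild-type library on the horizontal axis and in the Brg1 knockout library on the vertical axis; the line marks equal values. Red points (2139) are at least 2-fold higher and blue points (1151) at least 2-fold lower in the knockout library, with Gli1, Gli2, Mycn, Atoh1 and Smarca4 among the blue points.

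Hedgehog pathway genes were lower in the knockout library. Of 18 expressed components and targets, 11 were at least 2-fold lower and 0 higher, and the list median was -1.26 (percentile 0.0). Markers of mature cells were higher in the same library, with a median of 4.87 for Purkinje cells and 2.76 for the oligodendrocyte lineage. Gli1, a transcription factor and target of the pathway, had 89.2 FPKM in the wild-type and 9.03 FPKM in the knockout library (log2 ratio -3.17). Gli2, the main activator of Hedgehog transcription, went from 16.9 to 1.62 FPKM (log2 ratio -2.77). The oncogene Mycn had 85.8 and 8.52 FPKM (log2 ratio -3.19). The cyclin genes Ccnd1 (107.1 and 16.6 FPKM, log2 ratio -2.62) and Ccnd2 (158.7 and 58.8 FPKM, log2 ratio -1.42) were also lower. Ptch1, a receptor and target of the pathway, stayed within 2-fold, with 65.1 and 46.5 FPKM (log2 ratio -0.48). The 5 genes of the human SHH subgroup classifier had a median of -1.07 (percentile 0.41), with Atoh1, Sfrp1 and Hhip at least 2-fold lower; the first list also holds Sfrp1 and Hhip. Genes of the primary cilium, the organelle in which Hedgehog signals are transduced, did not stand apart (median 0.07, percentile 50.91), with 1 of 22 higher and 0 lower, and Ift27 had 52.1 and 42.7 FPKM and Ift20 had 22.03 and 27.7 FPKM.

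**Figure D2:**
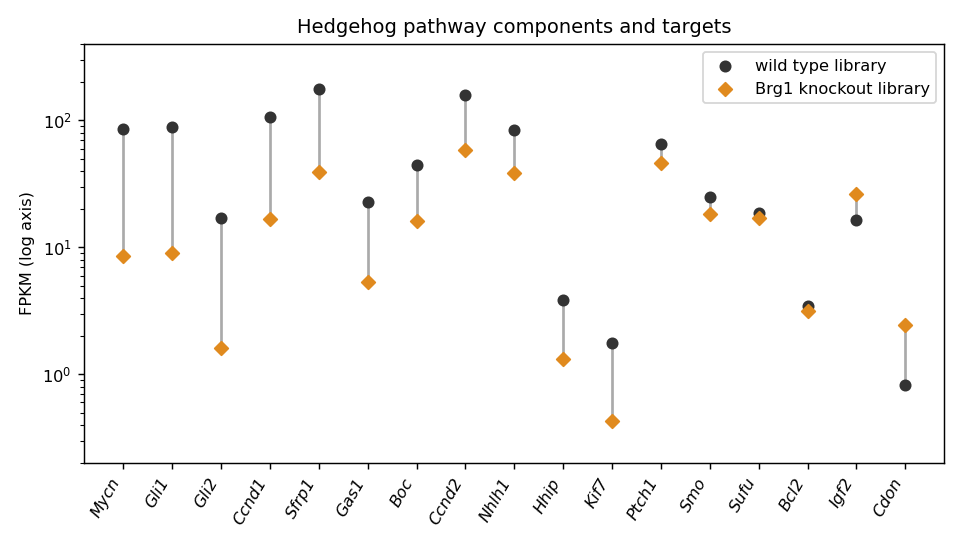
FPKM on a log axis for 17 of the 18 expressed Hedgehog components and targets, with the wild-type library as circles and the Brg1 knockout library as diamonds, joined by a line for each gene. Genes run from the lowest log2 ratio (Mycn, -3.19) on the left to the highest on the right.

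Of 38 cell cycle genes, 37 were at least 2-fold lower in the knockout library and 0 higher (median -1.85, percentile 0.0). Purkinje cell (median 4.87), GABAergic interneuron (3.53) and astrocyte (1.42) markers were higher in the same library. Mki67, a marker of dividing cells, had 40.8 FPKM in the wild-type and 10.2 FPKM in the knockout library (log2 ratio -1.90). Ube2c, which acts in mitotic exit, had 180.2 and 23.8 FPKM (log2 ratio -2.87). Aurkb, a mitotic kinase, had 39.0 and 5.63 FPKM, Mcm6 of the replicative helicase had 62.0 and 9.56 FPKM, and the transcription factor E2f1 had 57.2 and 9.65 FPKM. Of 67 replication-dependent histone genes only 11 were expressed, so the change of most of them cannot be read here. These 11 did not stand apart (median -0.06, percentile 16.24), and 3 were lower, Hist1h4i (5.25 and 1.18 FPKM), Hist1h2af and Hist1h4d. The p53 targets and cyclin-dependent kinase inhibitors did not stand apart either (median -0.22, percentile 10.76), but they did among genes of at least 5 FPKM (median -0.565, percentile 0.56). Among these 19 genes, Cdkn2a (9.33 and 1.67 FPKM), Trp53 (91.9 and 24.6 FPKM), Cdkn2c and Eda2r were lower, and Fas (1.14 and 5.45 FPKM) was higher. Cdkn2c and Eda2r lay close to the cutoff, with log2 ratios of -1.05 and -1.003, and Cdkn2c had -0.89 with FPKM rescaled to the same sum.

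Genes of granule neuron precursors, from which this tumour type arises, did not stand apart as a list (median -0.38, percentile 5.60). Of 15 genes, 2 were at least 2-fold lower and 0 higher. These were Atoh1, the transcription factor that defines the precursors, with 67.0 and 10.4 FPKM (log2 ratio -2.58), and Hes1, with 16.2 and 5.12 FPKM (log2 ratio -1.49). Granule neuron differentiation genes (median 2.68) and astrocyte and Bergmann glia markers (1.42) were higher in the same library. Whether members of the precursor list are limited to precursors was not examined, so its median does not show that precursor identity was kept.

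Genes of granule neuron differentiation were higher in the knockout library, 17 of 23 by at least 2-fold, with a median of 2.68 (reached by 0 of 10000 random lists). Gabra6, a GABA receptor subunit gene of mature granule neurons, had 1.24 FPKM in the wild-type and 143.1 FPKM in the knockout library (log2 ratio 6.01). Cbln3 had 0.916 and 58.4 FPKM. Dcx, 1 of the 17, was listed at 0 in the wild-type library with the status FAIL, so no fold is given. Without records of status FAIL or LOWDATA, an alternative chosen after seeing the data, the list median was 2.275. Nfia was the 1 member at least 2-fold lower (log2 ratio -1.88). Markers of other mature cerebellar cells were higher in the same library: the Purkinje cell median was 4.87 and the oligodendrocyte lineage median 2.76.

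All 10 expressed Purkinje cell markers were at least 2-fold higher in the knockout library (median 4.87, reached by 0 of 10000 random lists). Pcp2 had 0.644 FPKM in the wild-type and 147.5 FPKM in the knockout library (log2 ratio 6.50), Calb1 had 1.33 and 149.4 FPKM (log2 ratio 6.01), Car8 had 1.32 and 86.3 FPKM, and Rgs8 had 0.597 and 60.6 FPKM. All 7 GABAergic interneuron markers were higher (median 3.53, reached by 0 of 10000 random lists), among them Gad1 (1.80 and 77.1 FPKM), Pvalb (10.9 and 293.8 FPKM), Slc32a1 and Gad2; Gad1 is in both lists. All 5 unipolar brush cell markers were higher (median 2.81, reached by 0 of 10000 random lists), with Calb2 at 1.99 and 38.3 FPKM and Plcb4 at 1.27 and 14.99 FPKM. Of 10 forebrain and midbrain neuron markers 5 were expressed, with a median of -1.10 (percentile 0.18), and with no filter on low values the list did not stand apart (median -0.009, percentile 12.54). Of the 5 genes 3 were at least 2-fold lower, among them Lhx2 (9.55 and 2.67 FPKM) and Pou3f4 (log2 ratio -1.10, but -0.91 from the bound midpoints), and Otx1 (0.290 and 2.07 FPKM) was higher.

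Glial markers were also higher in the knockout library. Of 12 astrocyte and Bergmann glia markers 9 were at least 2-fold higher (median 1.42, percentile 99.99), with Gfap at 83.5 and 628.8 FPKM, Aldoc at 64.6 and 911.9 FPKM, Gja1 at 17.6 and 138.1 FPKM, and Gdf10 at 6.26 and 47.7 FPKM. Fabp7, which is expressed in radial glia, went the other way, from 425.4 to 86.0 FPKM. In the oligodendrocyte list 8 of 13 genes were higher and 3 lower (median 2.76, reached by 0 of 10000 random lists). The higher genes included the myelin genes Mbp (31.1 and 351.1 FPKM), Mobp (0.505 and 26.1 FPKM) and Mal (1.10 and 36.2 FPKM). The lower genes were the precursor genes Olig2, Pdgfra and Olig1, with log2 ratios of -2.07, -1.51 and -1.30.

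Of 15 microglia and macrophage markers 9 were at least 2-fold higher (median 1.21, reached by 0 of 10000 random lists), with Csf1r at 10.4 and 36.7 FPKM, Mrc1 at 0.966 and 10.4 FPKM, Itgam at 0.605 and 5.38 FPKM, and Tmem119 at 1.56 and 5.57 FPKM. The 3 expressed erythroid genes were higher (median 1.61, percentile 98.45), Hba-a2 with 3.19 and 11.7 FPKM, together with Hbb-b2 and Alas2, but with no filter on low values the list did not stand apart (median 0.070, percentile 93.94). Markers of endothelial cells (3 of 11 higher, median 0.73, percentile 93.46) and of pericytes, fibroblasts and meninges (4 of 13 higher, median 0.82, percentile 97.34) did not stand apart. Among genes of at least 5 FPKM both did, with medians of 1.336 (percentile 98.57) and 1.762 (percentile 99.98). The endothelial median then rests only on Cldn5, Slco1c1, Slc2a1 and Ly6c1 (log2 ratios 0.39, 0.73, 1.95 and 2.60). In the pericyte list Col1a2 and Slc6a13 reached 5 FPKM only in the knockout library, so this filter kept them because they were higher there. Endothelial Ly6c1 had 10.2 and 66.5 FPKM, Slc2a1 had 10.3 and 42.5 FPKM, and Pecam1 had 1.29 and 4.27 FPKM. In the pericyte list Vtn had 7.34 and 37.8 FPKM, Dcn had 18.7 and 71.6 FPKM, and Slc6a13 and Col1a2 were also higher. Choroid plexus and ependyma markers did not stand apart (0 of 7 past the cutoff, median 0.06, percentile 42.75), with Ttr at 997.4 and 1069.9 FPKM. Otx2, with 40.9 and 20.4 FPKM, lay just inside the cutoff through the added 1 FPKM (log2 ratio -0.97) and past it from the bound midpoints (-1.06). Only 2 lymphocyte markers were expressed, Cd4 (1.43 and 1.78 FPKM) and Cd79a (1.08 and 0.359 FPKM), and 0 skeletal muscle markers.

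**Figure D3:**
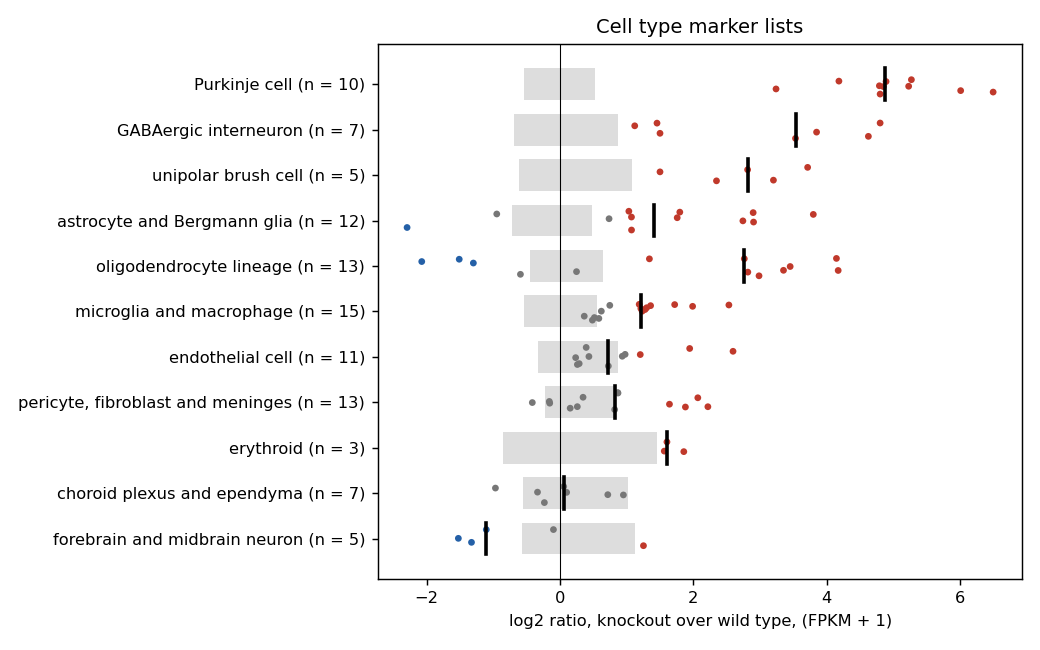
Log2 ratios of knockout over wild-type FPKM + 1 for the markers of each cell type, 1 point per gene, with the list median as a black bar and the central range of 10000 matched random lists (95% of them) in grey. Red points are at least 2-fold higher and blue points at least 2-fold lower; the Purkinje cell median lies at 4.87 and the choroid plexus median at 0.06.

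Genes of the Notch pathway were lower in the knockout library, 7 of 15 by at least 2-fold, with 1 higher (Jag2; median -0.68, percentile 0.02). Purkinje cell (median 4.87), oligodendrocyte lineage (2.76) and astrocyte (1.42) markers were higher in the library in which the Notch list and the Wnt list were lower. Dll3, a Notch ligand gene, had 27.04 and 1.002 FPKM (log2 ratio -3.81, or -2.98 from the midpoints of the deposited bounds). The target Hes5 had 17.6 and 0.984 FPKM (log2 ratio -3.23, or -2.76 from the midpoints). The ligand gene Jag1 had 13.8 and 2.56 FPKM, and Nrarp had 17.1 and 3.67 FPKM. With no filter on low values this list no longer stood apart (median -0.13, percentile 6.78). Wnt pathway targets and regulators were lower, 6 of 11 by at least 2-fold with 1 higher (Dkk3; median -1.01, percentile 0.0). The secreted Wnt inhibitors Sfrp2 (28.8 and 2.17 FPKM) and Wif1 (14.1 and 1.09 FPKM) were among them, as were Nkd1 (36.6 and 8.44 FPKM) and Apcdd1. The 3 expressed genes of the human WNT subgroup classifier had a median of -0.91 (percentile 2.31), with Wif1 lower and Gad1, which is also a Purkinje and interneuron marker, higher. Their mean was 0.35, so the list has no single direction. The Group 3 and Group 4 classifier had a median of 1.18 (percentile 98.21), with Kcna1, Eomes and Unc5d higher and Mab21l2 lower. Without Kcna1 (0.394 and 13.97 FPKM) its median was 0.47 (percentile 64.28), and with no filter on low values it was 0.22 (percentile 65.99).

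Of 13 BMP and TGF-beta pathway genes 5 were at least 2-fold higher and 0 lower (median 0.83, percentile 98.14), in the library in which astrocyte and Bergmann glia markers (median 1.42) and Purkinje cell markers (4.87) were also higher. These included the inhibitor of differentiation genes Id4 (3.13 and 35.8 FPKM), Id2 (61.2 and 235.4 FPKM), Id3 (37.3 and 100.9 FPKM) and Id1 (12.7 and 30.6 FPKM). Without Id4 the percentile was 96.96 and the list no longer stood apart. The list of Hippo pathway targets did not stand apart (median 0.36, percentile 79.82). It also holds the transcription factors Tead1 and Tead2 and the coactivators Yap1 and Wwtr1, through which the pathway acts. The targets Ctgf (0.889 and 6.87 FPKM), Axl and Cyr61 (log2 ratio 1.06, close to the cutoff) were higher. The lower members were Tead2 (53.3 and 11.7 FPKM) and Tead1 (30.8 and 8.66 FPKM).

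BAF complex genes other than Smarca4 did not stand apart as a list (median -0.20, percentile 7.10), with 3 of 27 higher and 2 lower. From the midpoints of the deposited bounds the median was -0.45 (percentile 0.24). Actl6b (6.16 and 16.4 FPKM), a subunit of the neuronal BAF complex, was higher, as were Smarcd3 (2.88 and 9.07 FPKM) and Dpf3 (0.088 and 1.65 FPKM). Bcl11a (15.5 and 3.58 FPKM) and Bcl11b were lower. Polycomb and H3K27 demethylase genes had a median of -0.47 (percentile 0.29), although only 1 of 21, Cbx2 (17.7 and 3.35 FPKM), was at least 2-fold lower. Cbx7 (2.15 and 8.08 FPKM) and Ezh1 (5.42 and 12.3 FPKM) were higher, but Ezh1 fell inside the cutoff after centring on the median (log2 ratio 0.97) and from the bound midpoints (0.93). With the mean in place of the median this list no longer stood apart (-0.28, percentile 2.96). Purkinje cell (median 4.87) and oligodendrocyte lineage (2.76) markers were higher in the library in which the Polycomb list was lower. None of 39 Hox cluster genes (0) reached 1 FPKM in either library.

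**Figure D4:**
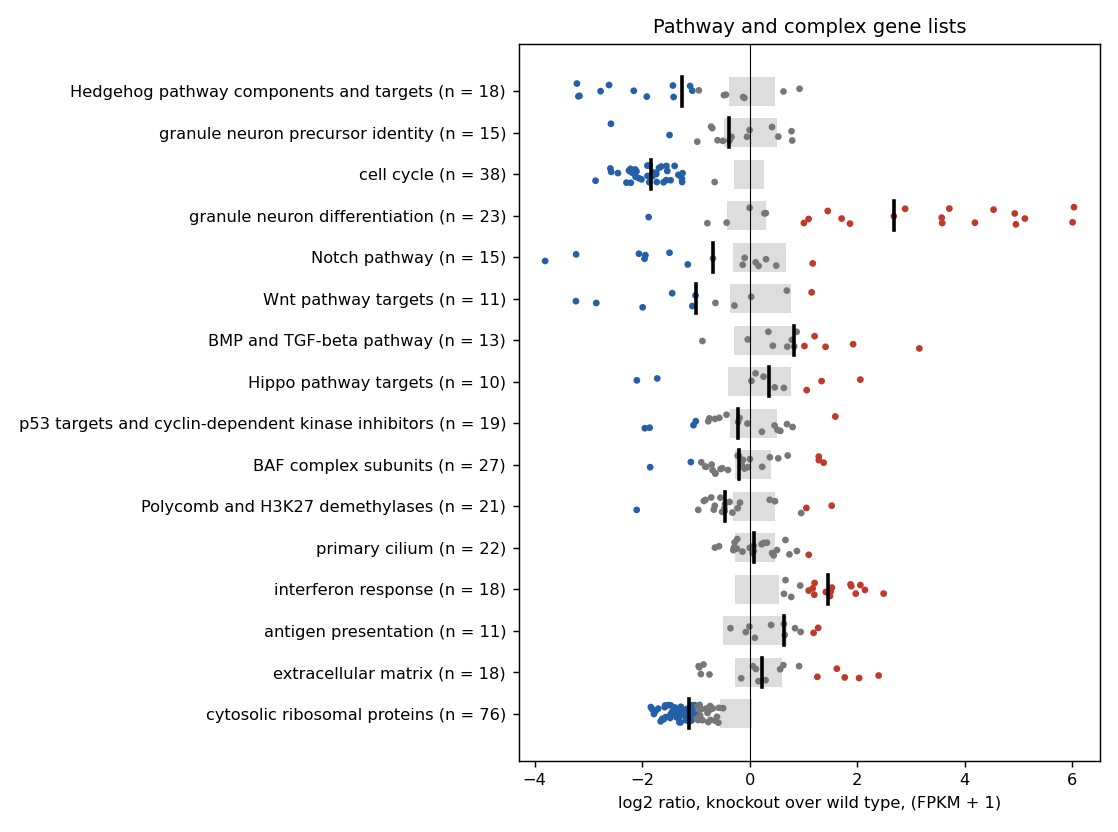
Log2 ratios of knockout over wild-type FPKM + 1 for pathway and complex lists, 1 point per gene, with the list median as a black bar and the central range of 10000 matched random lists (95% of them) in grey. Red points are at least 2-fold higher and blue points at least 2-fold lower; medians run from -1.85 for cell cycle genes to 2.68 for granule neuron differentiation.

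Interferon response genes were higher in the knockout library, 14 of 18 by at least 2-fold (median 1.45, reached by 0 of 10000 random lists). Ifit3 had 3.73 and 25.6 FPKM, Rsad2 had 1.38 and 9.53 FPKM, Usp18 had 1.80 and 10.7 FPKM, and Ifit1 had 0.862 and 6.32 FPKM. Microglia and macrophage markers were higher in the same library (median 1.21). Antigen presentation genes did not stand apart (2 of 11 higher, median 0.64, percentile 96.24), with H2-K1 at 36.3 and 89.2 FPKM and H2-D1 at 51.5 and 118.7 FPKM. Extracellular matrix genes did not stand apart either (5 of 18 higher, 0 lower, median 0.23, percentile 68.64). Sparc (104.5 and 556.2 FPKM), Timp1 (12.3 and 53.5 FPKM), Lama2, Spp1 (38.2 and 119.6 FPKM) and Fn1 were higher.

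Among single genes of at least 5 FPKM, Hsd11b2, which encodes an enzyme that inactivates glucocorticoids, had the lowest log2 ratio after Xist, with 233.1 FPKM in the wild-type and 2.89 FPKM in the knockout library (-5.91). The transcription factor gene Sox18 had 145.2 and 5.06 FPKM (log2 ratio -4.59), and the splicing factor gene Cwc22 had 102.3 and 3.55 FPKM (log2 ratio -4.51). From the midpoints of the deposited bounds the log2 ratios were -5.18 for Hsd11b2, -3.91 for Sox18 and -4.53 for Cwc22. Rprml, Smoc1, Shisa2 and Cxcr4, the chemokine receptor gene of granule precursors, had log2 ratios of -3.91, -3.68, -3.62 and -3.65. Rpl34-ps1 (13.2 and 0.008 FPKM) is uncertain, since a pseudogene can share reads with its parent gene. Among the highest ratios, Gng13 (2.62 and 143.1 FPKM, log2 ratio 5.31) and Fam107a (1.46 and 143.2 FPKM, log2 ratio 5.87) were in none of the gene lists. Whether these genes mark mature neurons or glia was not examined. Their values therefore cannot be set apart from the higher markers of those cells. Nono was listed at 0 in the wild-type library with the status FAIL, and the short record AF357425 was listed at 0 there too, so no fold is given for them.

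Several measures of the samples differed along with the genotype. Xist, which is transcribed from the inactive X chromosome of females, had 268.3 FPKM in the wild-type library and 0.369 FPKM in the knockout library (log2 ratio -7.62). The Y-linked genes Eif2s3y (0.026 and 63.4 FPKM), Ddx3y (0.007 and 25.1 FPKM) and Kdm5d were higher in the knockout library, and Uty was listed at 0 in the wild-type library and at 8.78 FPKM in the knockout library. The 5 expressed genes of this list had a median of 3.29 (reached by 0 of 10000 random lists). Cytosolic ribosomal protein genes were lower, 52 of 76 by at least 2-fold (median -1.13, percentile 0.0), with Rps20 at 756.5 and 210.7 FPKM, followed by Rps12. Immediate early and heat shock genes had a median of 0.80 (percentile 98.75): Hspb1 (1.30 and 23.3 FPKM), Fos (1.53 and 13.0 FPKM), Egr1, Junb and Nr4a1 were higher and Jun and Ier2 lower, close to the cutoff (log2 ratios -1.01 and -1.03). Without Hspb1 their median was 0.54 (percentile 93.06), and with no filter on low values it was 0.22 (percentile 85.18). Mitochondrially encoded genes had 0 records in the table. Medians of the 19 autosomes ran from -0.03 to 0.21, with chromosomes 6, 7, 12 and 17 outside the percentile limits (4 of 19), and chromosome X had a median of 0.18 (percentile 95.51).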

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

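The tests in this part were chosen after the values had been seen. In the deposited tables the FPKM lay outside its own lower and upper bound for 52.5% of the records of at least 1 FPKM in the wild-type library (6301 of 12006) and for 52.0% in the knockout library (6752 of 12994). This stands out because the bounds are deposited beside the values and were not part of the comparison. It held for 57.96% and 57.4% of records with 1 start site, against 6.70% and 7.30% of records with several. Across 11721 genes the log2 deviation of FPKM from the midpoint of its bounds was correlated between the libraries (Pearson r = 0.974, across genes, which are not independent replicates). Log2 ratios from FPKM and from the midpoints had r = 0.941 across the expressed records. No cause was tested.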

How the results depend on the processing

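The midpoints of the bounds, the removal of FAIL and LOWDATA records and the removal of genes at several loci were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library, and for the same reason no replicate could be left out. Smarca4, the Hedgehog list, the cell cycle list and the granule neuron differentiation list kept their direction and their side of the threshold under each alternative run. At 1.5-fold, 3727 records were higher and 2386 lower; at 4-fold, 554 and 199. The other 22 alternative counts stayed within 1.5 times the reported counts, and centring on the median gave 1875 higher and 1349 lower (58.2% higher). The 2 counts with no filter on low values could not change, since with the added 1 FPKM a 2-fold call needs at least 1 FPKM in 1 library. The granule precursor list stood apart (percentile 2.06) only against random lists not matched on expression, with its median of -0.377. From bound midpoints Smarca2 had a log2 ratio of -1.485, and with the mean in place of the median the WNT classifier had 0.346; the cause of these was not tested. Of all alternative list values 433 kept their call, 15 lost it, 9 gained it and 1 turned. Of those for single genes 1449 kept it, 4 lost it, 4 gained it and 1 turned. Filters and the removal of records leave the log2 ratio of a remaining gene, Smarca4 included, unchanged, so its call was kept there by construction. The count of 1449 therefore overstates how far single genes were tested. With no filter the Notch, erythroid, forebrain and both other classifier lists and the immediate early list no longer stood apart, since members near 0 FPKM then enter. Depth is unknown and the way the deposited bounds were made is not given, so the precision of low values is not known.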

Other observations

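The gene families in this part and all 7 tests below were chosen after the values had been seen. Families were defined by symbol pattern, 27 in all: 11 lay above and 5 below the percentile limits. Since the patterns were chosen after the values were seen, no number expected by chance can be set beside this count. Mature neuron markers were higher in the knockout library, with medians of 4.87 for Purkinje cells and 3.53 for GABAergic interneurons, beside the values of the families that follow. Of 53 genes with potassium channel symbols (Kcn) 27 were at least 2-fold higher and 2 lower (median 1.06), with Kcnt1 at 0.944 and 26.4 FPKM. Sodium channel genes had a median of 2.51 (5 of 8 higher), calcium channel genes 0.76 (9 of 21 higher, 1 lower), GABA receptor genes 2.66 (8 of 10 higher), glutamate receptor genes 1.02 (10 of 19 higher), synaptotagmins 1.26 (9 of 15 higher, 2 lower) and protocadherins 0.83 (16 of 55 higher, 1 lower). These medians stayed above 0 under rescaling to a common sum, upper quartile scaling, centring and bound midpoints.

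Metallothionein genes, which encode metal-binding proteins, were higher in the knockout library, Mt2 with 252.3 and 4317.8 FPKM and Mt1 with 244.4 and 3027.6 FPKM (median of 3 genes 3.63). Of 27 genes with symbols of chemokines or their receptors, 1 of which (Ccrn4l, within 2-fold) is neither, 16 were higher and 1, Cxcr4, lower (median 1.28), with Ccl12 at 7.05 and 45.4 FPKM. Of 22 genes with symbols of the complement and serpin pattern, which also took Serp1 and Serp2 (both within 2-fold, and of neither family), 13 were higher and 1 lower (median 1.18), with Serpina3n at 9.69 and 180.3 FPKM. Microglia and macrophage markers (median 1.21) and astrocyte and Bergmann glia markers (median 1.42) were higher in the same library. Of 11 SR splicing factor genes 6 were lower and 1 higher (median -1.09, below 0 under each scaling), with Srsf2 at 373.1 and 124.8 FPKM; the higher one, Srsf11, is listed at 0 in the wild-type library with a failed status. Solute carriers had a median of 0.40, mitochondrial ribosomal proteins -0.36, zinc finger genes -0.21, Dnmt and Tet genes -0.60 and patterning genes -0.37. The other 11 families did not stand apart, among them complex I genes (0.12) and genes of the forkhead pattern (-0.05). The forkhead pattern also took Foxred1 and Foxred2, and the patterning pattern took Paxip1, which are not of these families.

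Mature neuron and glia genes were higher in the knockout library. A lower tumour share with other cell types in fixed proportion would raise their markers alike. The lower quartile of the Purkinje list lay 3.70 above the upper quartile of the endothelial list on the log2 scale. The added 1 FPKM shrinks the ratios of low endothelial genes. Without it, the median knockout values were 5397.3% (Purkinje) and 174.7% (endothelial) of wild type, so these 2 lists did not rise alike. They were picked after their values were seen, so they give no verdict on this explanation as a whole. Mature cerebellar tissue in the knockout sample is a candidate explanation: Purkinje cells lie outside the granule lineage, and their markers had a median of 4.87, with all 10 above 0. Differentiation of tumour cells into granule neurons stays open beside it, since that list was higher (median 2.68) but so were those of neurons outside the lineage, and these cannot be told apart here.

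Some genes had a lower ratio of knockout to wild type than every one of the 38 cell cycle genes, whose knockout values were 13.2% to 56.7% of wild type (median 24.8%). Dilution of tumour cells of unchanged profile by tissue that does not divide would bring no gene far below these. Of 7929 genes 43 lay below the lowest cell cycle ratio and 13 below 6.6%, among them Hsd11b2, Sox18, Dll3 and Hes5, while Gli1, Gli2 and Mycn lay between 9.6% and 10.1%. These counts decide nothing, since they take the extreme genes of the pattern itself, and the limit of 6.6% and the removal of sex-linked, unnamed, pseudogene and failed records were settled after a first count of 53. Dilution therefore stays open, and a difference between individual tumours cannot be told apart from the genotype with 1 library of each.

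Xist and the Y-linked genes differed between the libraries. An exchange of the labels would put Smarca4 higher in the library labelled knockout if the 2 samples held the same cells. Its log2 ratio there was -1.66, or 26.8% of wild type, inside the range of the cell cycle genes (13.2% to 56.7%). A different cell content could lower Smarca4 under either labelling, so this value cannot decide on an exchange. Animals of different sex are a candidate explanation, with Xist at -7.62 and each expressed Y-linked gene at least 10 times higher in the knockout library. Genotype and this difference in sex-linked genes are confounded in every comparison above. The 4 expressed genes within 1 Mb of Cwc22 had log2 ratios of -0.10 to 1.45, so its low value was not shared by its neighbours.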
